A study of Mus musculus with 4 samples.

How the data were processed

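Total RNA from flow-sorted CD8+ T cells with high CD11a, 1 ng per library, was made into cDNA with the SMARTer Ultra Low kit and sequenced on an Illumina HiSeq instrument as paired-end reads of 101 bases, per the labels' protocols. Base calls were converted with bcl2fastq 1.8.4 and reads were aligned to hg38 with TopHat2, whose version is not given, per the submitters' processing notes. The counting tool, the strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited files hold raw counts per Ensembl gene, per the column headers and the whole-number values, 1 file per library, with 64253 genes in each. The amplified cDNA carried no stated molecular identifiers, so counting intervals and floors cover counting error only. With so little input RNA, a count of 0 can also come from a transcript that was never captured.

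The 4 libraries were placed in groups from their labels: responder or non-responder, before or after therapy. One treatment label says that blood was taken after a cycle of therapy for every sample, whereas the group label says that 2 of the 4 libraries are from before therapy, and the group label was followed. No replicate exists within a group. Genes on alternate or unplaced contigs, 4146 in number, and 617 sex-informative genes were left out of all tables and tests, which leaves 59490, while library totals include all counts. The symbols CCR6, IRF9 and SDHD each stand on 2 entries, and the gene was used in place of the overlapping read-through entry. No annotation of gene biotype was used, since the reference at hand was of mouse. Gene symbols and coordinates are those of the files, with coding lengths as the files give them.

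The test for response and for time used edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr, an additive model of response and time over all 4 libraries, and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model leaves 1 residual degree of freedom and treats the interaction of response and time as error. The common biological coefficient of variation was 0.66. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run on the same design. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. P-values measure only the spread between these libraries. The SE printed with a fitted log2 ratio is the size of that ratio divided by the square root of its F statistic, not a separately estimated error.

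Comparisons of 1 library with another used log2 ratios of TMM-normalised CPM with a prior count of 0.5 and exact conditional binomial 95% intervals. Genes at least 2-fold apart were counted among those with at least 5 CPM in either library. A gene with no count in a library was given a bound against a floor of 3 counts in that library, which is 0.036, 0.046, 0.0235 and 0.0268 TMM-normalised CPM in the responder and non-responder libraries before therapy and the responder and non-responder libraries after therapy. The 25 gene lists were fixed before the data were examined, and 440 of their 445 genes were found in the files. Each list's median over members with at least 1 CPM in at least 1 of the 4 libraries was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and lists under percentile 2.5 or over 97.5 are called outside the random range.

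Genes named in the text follow a rule written before the data were examined. It takes the sort markers first, and up to 4 members with the largest ratio in each list described. It then takes the 10 genes per direction with the largest smaller ratio over both pairs, and the 5 genes per direction with the largest ratio in each pair, from genes with at least 5 CPM and 50 reads in the higher library. Some genes that the rule takes are not reported here. Genes called by the additive model would have been named too, but there were 0. Receptor segment, HLA and KIR genes are not named under the last parts of the rule. NFKBIA, S100A8, S100A9, KRT7, KRT8, KRT18, FN1, ELF3, LAMB3, TYMP, CLEC12A, HYAL2 and ZNF607 were named outside this rule, after their values were seen, and so was the choice of genes for which a fitted ratio is printed.

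The fit was tested on simulated counts for the response comparison, with 200 genes changed and the real means and library sizes. At a coefficient of variation of 0.66, and over 24952 genes, 0% of 4-fold, 27.8% of 16-fold and 82.5% of 64-fold changes were recovered, with 2 false calls. At 0.1 all of the changed genes of each size were recovered among 25120 genes, with 6 false calls. For the comparison of times, 0%, 26.0% and 82.6% were recovered at 0.66 among 24928 genes. Simulated lists of 20 genes with no shift lay outside the random range in 3.5% of 200 trials, over 16449 genes.

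Alternatives were other scaling (DESeq2 size factors, library size only), other filters on low counts, other tests, no covariate, each library left out, another prior count and fold, and a matrix without mitochondrial, receptor and ribosomal protein genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for ratios and lists, and matplotlib 3.10.9 for figures.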

Results

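RNA was sequenced from CD8+ T cells with high CD11a, sorted by flow cytometry from the peripheral blood of patients treated with an antibody against PD-1. CD11a is the integrin chain encoded by ITGAL that marks antigen-experienced T cells, and PD-1 is an inhibitory receptor encoded by PDCD1. Per the labels, the antibody was given every 3 weeks, with 4 doses in a cycle. The 4 libraries formed 4 groups of 1 library each: a responder and a non-responder before therapy, and a responder and a non-responder after therapy. The labels do not say that the before and after libraries came from the same patients, and the series text speaks of 2 cohorts of patients without tying them to libraries, so a difference between before and after can also be a difference between patients or cohorts. The organism field of the labels names mouse, whereas the files hold human genes on the human build hg38 and the samples are described as patients, so the data were read as human.

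The responder library before therapy held 78912300 counts and the non-responder library before therapy 65500644. The responder library after therapy held 129773591 counts and the non-responder library after therapy 115446087. A count was present for 30272, 26352, 29311 and 29459 genes in these libraries, in the same order. Levels are given as CPM, the count scaled to a common library size after TMM normalisation, and each log2 interval is a 95% interval for counting error alone. Each group held 1 library, so no comparison of 1 library with another has a replicate check, and none has a p-value.

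The markers of the sort were abundant in all 4 libraries. CD8A (ENSG00000153563, chromosome 2: 86784610 to 86808396), a chain of the CD8 co-receptor, stood at 1110 CPM in the responder and 865 CPM in the non-responder before therapy, and at 1561 CPM and 946 CPM after therapy. CD8B lay between 598 and 692 CPM. The CD3 chain CD3E lay between 556 and 751 CPM, CD3D between 404 and 820 CPM, and CD3G between 150 and 296 CPM. ITGAL, the CD11a gene, lay between 516 and 765 CPM. PDCD1 (ENSG00000188389, chromosome 2: 241849881 to 241858908) stood at 31.4 CPM in the responder and 4.98 CPM in the non-responder before therapy, and at 28.7 CPM and 7.88 CPM after therapy. The sample names of both libraries from before therapy carry a PD-1-positive tag, and their PDCD1 levels were 6.29-fold apart (log2 ratio 2.65, 95% interval 2.49 to 2.83). The labels do not say whether these libraries were also gated on PD-1, so the gate is not known to be the same before and after therapy.

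The first comparison asked which transcripts separated responder from non-responder libraries at both times. Immediate early and NF-kB response genes, which T cells switch on within minutes to hours of stimulation or stress, were lower in the responder library at both times. The median log2 ratio of the 23 detected list members was -1.63 before and -1.31 after therapy, below all of 10000 random lists matched on expression, and 14 members were at least 2-fold lower at both times. NR4A2, an orphan nuclear receptor (ENSG00000153234), stood at 28.6 CPM in the responder against 341 CPM in the non-responder before therapy, and NR4A3 at 0.516 against 10.4 CPM. FOS, a subunit of the transcription factor AP-1, stood at 298 against 2850 CPM after therapy, EGR1 at 2.95 against 56.3 CPM, NR4A1 at 4.47 against 32.4 CPM, and DUSP1, a phosphatase that acts on MAP kinases, at 727 against 4190 CPM. XCL1, a chemokine on the same list, went the other way and was at least 2-fold higher in the responder at both times. Monocyte and neutrophil markers were also lower in the responder after therapy, with a median log2 ratio of -2.24. In that pair, monocyte RNA and a change within the T cells cannot be told apart.

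**Figure D1:**
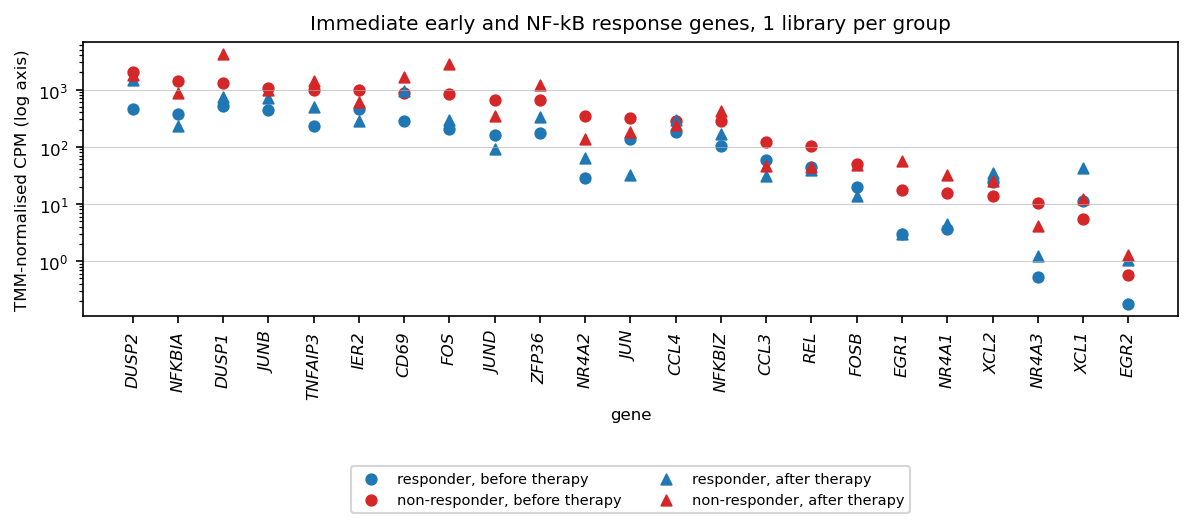
TMM-normalised CPM (log axis) of the 23 members of the immediate early and NF-kB response list in the 4 libraries, with 1 point per library. Circles are libraries from before therapy, triangles from after therapy, blue responder and red non-responder, and the blue points lie below the red ones of the same shape for most genes, for example NR4A2 at 28.6 against 341 CPM before therapy.

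Inhibitory receptor genes went the opposite way. PDCD1 is on this list, and whether the libraries from before therapy were also gated on PD-1 is not known. A part of such a gate in the difference before therapy therefore cannot be told apart. The median log2 ratio of the 17 detected members was 0.79 before therapy, at percentile 99.97 of the random lists, and 0.66 after therapy, at percentile 99.99, and 13 members were higher in the responder at both times. Before therapy, BTLA stood at 7.42 against 0.874 CPM and CD101 at 36.5 against 4.34 CPM, both receptors that dampen T cell signalling, while the transcription factor TOX2 was lower in the responder, at 0.997 against 3.88 CPM. After therapy, the checkpoint receptor TIGIT stood at 230 against 41.9 CPM and CD244 at 200 against 85.1 CPM.

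Genes of the CX3CR1-type effector memory list, which describes cytotoxic cells that patrol the blood, were also higher in the responder libraries. The median log2 ratio of the 17 members was 0.39 before therapy, at percentile 99.44, and 0.80 after therapy, at percentile 100. CX3CR1 itself (ENSG00000168329, chromosome 3: 39263494 to 39281735), the fractalkine receptor, stood at 679 CPM in the responder against 78.2 CPM in the non-responder before therapy, an 8.68-fold difference, and at 379 against 162 CPM after therapy, a 2.33-fold difference. S1PR1, which directs exit from lymph nodes, stood at 157 against 43.2 CPM before therapy, and KLRG1 at 462 against 161 CPM after therapy. The 16 cytotoxic effector genes had a median log2 ratio of 0.11 before therapy, within the random range at percentile 75.11, and of 0.91 after therapy, at percentile 100. PRF1, the pore-forming perforin, stood at 1613 against 685 CPM before and 1488 against 465 CPM after therapy. FASLG, the death ligand, stood at 48.3 against 7.96 CPM and 41.6 against 15.2 CPM. The cytokine genes IFNG and TNF were lower in the responder after therapy, at 22.5 against 84.3 CPM and 5.22 against 33.3 CPM. The sort and label list, with the CD3 and CD8 chains, ITGAL and PDCD1, also had higher medians in the responder. These were 0.36 before and 0.52 after therapy over 7 genes, both inside the random range, with 6 and 7 genes higher. Monocyte and neutrophil markers were lower in the responder after therapy, with a median of -2.24. Whether other cells' RNA adds to the effector and inhibitory receptor medians was not tested.

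**Figure D2:**
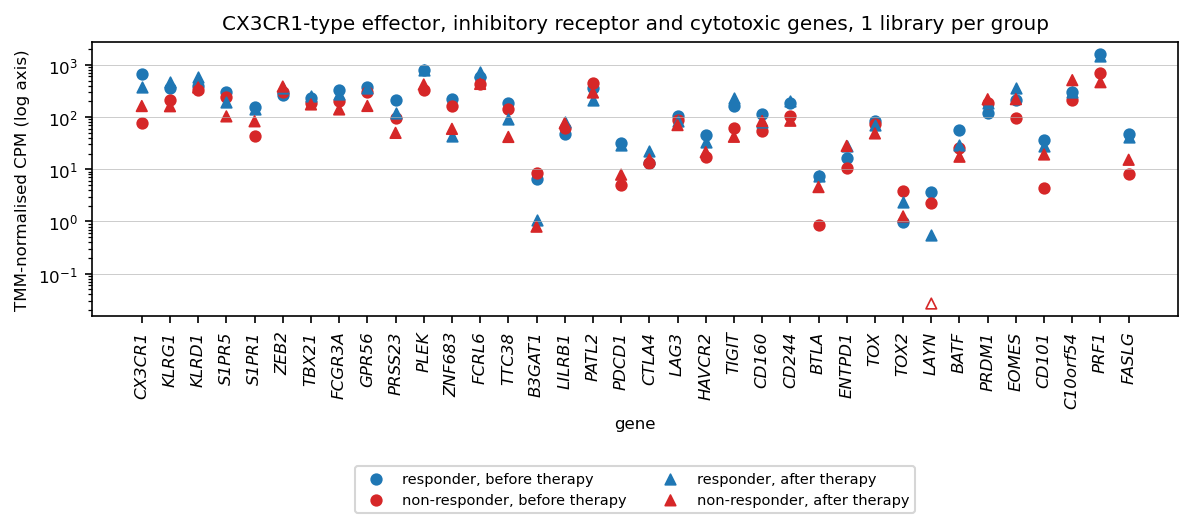
TMM-normalised CPM (log axis) of the detected members of the CX3CR1-type effector memory and inhibitory receptor lists, with PRF1 and FASLG, in the 4 libraries, with 1 point per library. Circles are libraries from before therapy, triangles from after therapy, blue responder and red non-responder, and the open symbol for LAYN marks a count of 0 drawn at the floor of 3 counts, while PDCD1 stands at 31.4 and 28.7 CPM in the responder libraries and at 4.98 and 7.88 CPM in the non-responder libraries.

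Other gene groups also stood apart. The 28 proliferation genes had a median log2 ratio of 0.42 before therapy, inside the random range at percentile 97.37, and of 0.70 after therapy, at percentile 99.99. After therapy, MKI67, a marker of dividing cells, stood at 8.91 CPM in the responder against 0.402 CPM in the non-responder, and CDC20 at 3.71 against 0.634 CPM, while AURKB, a mitotic kinase, was lower in the responder, at 0.228 against 0.795 CPM. Heat shock and stress genes were lower in the responder by their medians, -0.68 before and -0.35 after therapy over 21 members, both under percentile 0.1. Of these, 12 were lower and 3 higher in the responder at both times. DDIT3, a transcription factor of the unfolded protein response, stood at 56.1 against 201 CPM before therapy, and ATF3 at 0.706 against 17.9 CPM after therapy. The 15 mitochondrially encoded genes had medians of -0.65 and -0.60, and 14 of them were lower in the responder at both times, among them MT-CO3 at 2690 against 5370 CPM before therapy. Mitochondrial counts made up 4.03% of the responder and 5.43% of the non-responder library before therapy, and 3.37% and 4.75% after therapy. The nuclear RNA MALAT1 made up 1.47% and 4.23% of counts before therapy and 1.62% and 2.22% after it, and the 50 most abundant genes 18.3% and 21.9%, and 17.6% and 20.6%, so these shares too were lower in the responder, as were the immediate early, stress and mitochondrial medians. The 55 cytosolic ribosomal protein genes had a median of -0.25 at both times.

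Markers of other cell types also separated the same libraries. The 17 monocyte and neutrophil markers had a median log2 ratio of -0.46 before therapy, at percentile 1.1, and of -2.24 after therapy, below all random lists. LYZ, the lysozyme gene of monocytes and granulocytes, stood at 8.25 CPM in the responder against 35.1 CPM in the non-responder before therapy, and at 791 against 3631 CPM after therapy. The chemokine receptors CXCR1 and CXCR2, which cytotoxic lymphocytes also express, were at least 2-fold higher in the responder at both times. Platelet markers had medians of -0.84 before and -2.93 after therapy over 9 members, with PPBP at 10.8 against 29.1 CPM and 4.91 against 61.4 CPM. The 8 dendritic cell markers had a median of 0.10 before therapy, or 0.98 with library counts of 0 set at the floor, and of -3.35 after therapy, with CD1C at 0.392 against 13.3 CPM. Red cell markers, only 3 genes, had medians of -1.60 and 0.85, both inside the random range, with HBB at 0.216 against 15.5 CPM before therapy. The 10 NK cell markers had a median of 0.31 at both times, and the 12 B cell and plasma cell markers of 1.02 before and -0.91 after therapy, all inside the random range. The last value turned to 0.48 over the B cell and plasma cell markers with at least 10 CPM.

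Among single genes, those with the largest smaller ratio of both times were, on the side of the responder, NPTX1, PSMG3-AS1, UHRF1, ZNF343, CXCR1, EHHADH, ZFP57, POP1, KIF11 and LAPTM4B. KIF11, a spindle motor, was 4.17-fold higher in the responder before therapy (log2 ratio 2.06, interval 1.74 to 2.40) and 46.9-fold higher after therapy (5.55, interval 5.04 to 6.18). UHRF1, which maintains DNA methylation in dividing cells, stood at 10.1 against 1.01 CPM and 6.07 against 0.25 CPM. NPTX1 and EHHADH had no count in the non-responder library before therapy, so the responder level was at least 230-fold and at least 110-fold higher there, against a floor of 3 counts per library. These bounds cover counting error only, and a transcript that was not captured can also give a count of 0. On the side of the non-responder stood GRASP, IGJ, PER1, DAPK1, C2orf88, GNA15, MAFF, EGR1 and CD83. PER1 (ENSG00000179094), a circadian clock gene also induced by glucocorticoids, was 7.8-fold lower in the responder before therapy (log2 ratio -2.96, interval -3.03 to -2.90) and 10.4-fold lower after therapy (-3.38, interval -3.43 to -3.33). GRASP was 23.2-fold and 20.5-fold lower, and CD83 5.25-fold and 8.32-fold lower. PER1, MAFF and CD83 are not members of the immediate early list.

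The additive model, in which edgeR's quasi-likelihood test compared the responder with the non-responder libraries with time as a covariate, called 0 of 24113 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 2119 genes, and the lowest adjusted p was 0.558. DESeq2 on the same design called 896 genes, 421 higher and 475 lower in the responder libraries, and limma-voom called 0. In the edgeR fit PDCD1 was 2.26 ± 0.365 (log2 ratio ± SE, adjusted p = 0.558), PRF1 1.46 ± 0.204, TIGIT 1.93 ± 0.334, NFKBIA -1.92 ± 0.173 and PER1 -3.17 ± 0.222, each with the same adjusted p. Adjusted over the list alone, 18 of the 23 immediate early and NF-kB genes passed, 17 lower and 1 higher in the responder libraries, against 0 over all genes tested. Adjusted over the list alone, 8 of 15 mitochondrially encoded genes, 6 of 17 monocyte and neutrophil markers and 5 of 21 heat shock and stress genes also passed, the latter with 4 lower and 1 higher. PDCD1 and TIGIT passed among the inhibitory receptors, PRSS23 and PLEK among the CX3CR1-type genes and PRF1 among the cytotoxic genes. The set test camera, with a preset correlation of 0.01, called 15 of 25 lists, with an adjusted p of 9.47e-36 for the immediate early list (adjusted p = 0.632 with an estimated correlation), 5.76e-07 for inhibitory receptors (adjusted p = 0.632 with an estimated correlation) and 2.04e-07 for the CX3CR1-type list (adjusted p = 0.648 with an estimated correlation). No list kept its call with an estimated correlation, which was 0.004, -0.046 and 0.118 for these lists in the same order. The model had 1 residual degree of freedom, with which the test at an estimated correlation can hardly give a low p for any list. The loss of the calls therefore cannot decide, and the calls themselves rest on the preset value.

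Before therapy, 2521 of 12361 genes with at least 5 CPM in either library were at least 2-fold apart, 1417 higher and 1104 lower in the responder. The chemokine receptor CCR2 stood at 17.0 CPM in the responder and had no count in the non-responder library, at least 369-fold apart for counting error alone. A transcript that was not captured from 1 ng of input RNA can also give such a 0. CLDN4, PDLIM4 and CTGF likewise had no count in the non-responder library, and CLDN4, a tight junction gene of epithelia, stood at 16.3 CPM in the responder. Lower in the responder were RASD2, LONRF2, HBB, ARHGEF10 and PLXNA2, the last 66.3-fold (log2 ratio -6.05, interval -6.97 to -5.34). Glycolysis genes were higher in the responder before therapy, with a median of 0.53 over 19 members at percentile 99.94 and 12 higher at both times, while after therapy the median was 0.09 at percentile 50.5. PFKP, a phosphofructokinase, stood at 118 against 56.1 CPM before therapy, and the glucose transporter SLC2A3 was lower in the responder, at 162 against 358 CPM. The same responder library held epithelial transcripts such as CLDN4, and whether RNA of other cells adds to the glycolysis values was not tested. Apoptosis regulators had a median of -0.30 before therapy at percentile 1.86, with PMAIP1, a death-promoting BCL2 family gene, at 134 against 455 CPM, and of 0.01 after therapy. Chemokine receptors and integrins had medians of 0.32 and -0.05, and T cell activation genes of 0.34 and 0.19, all inside the random range. The chemokine receptor and integrin median after therapy turned to 0.45 over members with at least 10 CPM. CXCR6, a receptor of tissue-homing T cells, stood at 46.3 against 2.59 CPM before therapy.

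After therapy, 1821 of 12434 genes were at least 2-fold apart, 720 higher and 1101 lower in the responder. KIF11, MTRNR2L8, ZNF620, MDGA1 and ZNF77 were highest relative to the non-responder, with MDGA1 29.2-fold higher. MTRNR2L8, a nuclear near-copy of the mitochondrial ribosomal RNA gene, was 34.4-fold higher. GUCY1B3, ABO, ITGB5, KIT and SAMD4A had no count in the responder library, and GUCY1B3 was at least 313-fold lower there. Interferon-stimulated genes had a median of 0.11 before therapy, inside the random range, and of -0.25 after therapy, at percentile 0.05, with 8 of 30 members at least 2-fold lower and 0 at least 2-fold higher in the responder. IFIT1 stood at 3.81 against 22.0 CPM after therapy and IFI44L at 13.1 against 70.6 CPM. The monocyte and neutrophil markers were lower in the same responder library, with a median of -2.24, and which cells these transcripts came from was not tested. RSAD2, another interferon-stimulated gene, was higher in the responder before therapy, at 7.17 against 1.04 CPM. Naive and central memory genes had a median of 0.18 before therapy, inside the random range, and of -0.26 after therapy, at percentile 0.83. CCR7, a lymph node homing receptor, stood at 164 CPM in the responder against 61.8 CPM in the non-responder before therapy. Among gamma-delta T cell constant genes, 3 in number, TRDC was 3.76-fold higher in the responder after therapy, at 93.9 CPM, and the median was 0.74 at percentile 98.44, against 0.11 before therapy. The respiratory chain genes encoded in the nucleus had medians of -0.07 and -0.02, both inside the random range.

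Across 11562 genes, the responder to non-responder ratios before and after therapy had Pearson r = 0.349 and Spearman rho = 0.429, and 66.7% had the same sign. These values are across genes, which are not independent replicates, and both ratios use different libraries. Genes at least 2-fold higher in the responder at both times numbered 213, against 67.3 for independent lists, and those at least 2-fold lower numbered 232, against 47.0. A further 76 genes were at least 2-fold apart in opposite directions, against 115.0 for independent lists. The after to before ratios of responders and non-responders, from libraries that differ in monocyte markers, had r = 0.508 across 11673 genes. Agreement across genes thus does not tell its cause.

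**Figure D3:**
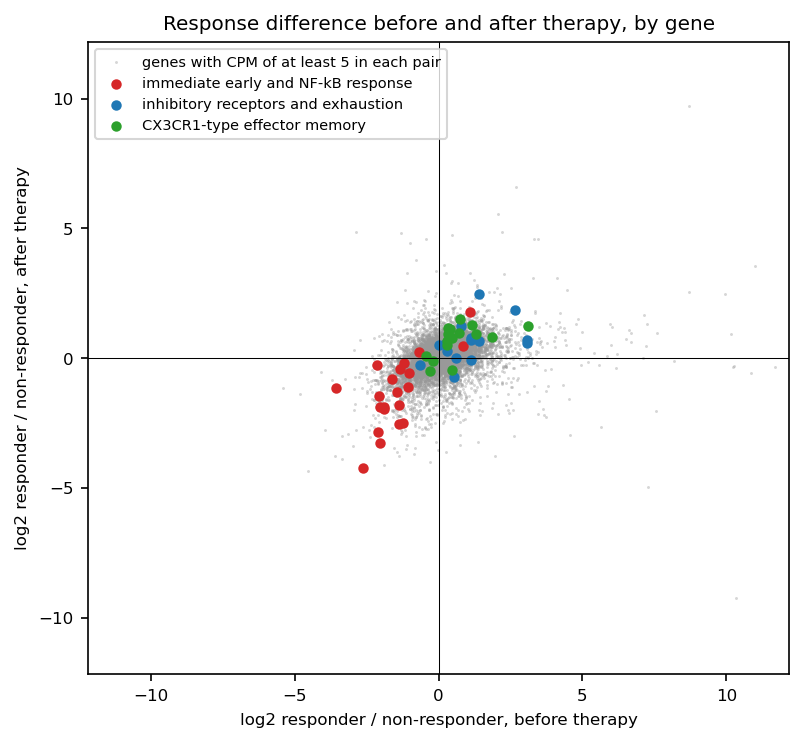
log2 ratio of responder to non-responder before therapy (x axis) against the ratio after therapy (y axis), with 1 point per gene with at least 5 CPM in either library of each pair. Red points are immediate early and NF-kB genes, mostly in the lower left, blue points inhibitory receptors and green points CX3CR1-type genes, mostly in the upper right, and r across all 11562 genes was 0.349.

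The second comparison set libraries from after therapy against those from before it. Monocyte and neutrophil markers were far higher after therapy in both response groups, with a median log2 ratio of 3.39 in responders and 5.22 in non-responders, above all random lists, and 15 of 17 at least 2-fold higher in both. LYZ was 95.8-fold higher in responders (log2 ratio 6.58, interval 6.47 to 6.69) and 104-fold higher in non-responders (6.69, interval 6.64 to 6.75). CLEC7A, a fungal pattern receptor of myeloid cells, was 80.5-fold higher in responders, and S100A12 was 123-fold higher in non-responders. The genes named by their ratio in both groups were DOK3, VSIG4, NFAM1, CD86, KCTD12, LYZ, CLEC7A, PLBD1, TNS3 and ASGR2, of which LYZ and CLEC7A are on the monocyte and neutrophil list. DOK3 and VSIG4 had no count in either library from before therapy, and DOK3 was at least 182-fold higher in responders and at least 840-fold higher in non-responders, for counting error alone.

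**Figure D4:**
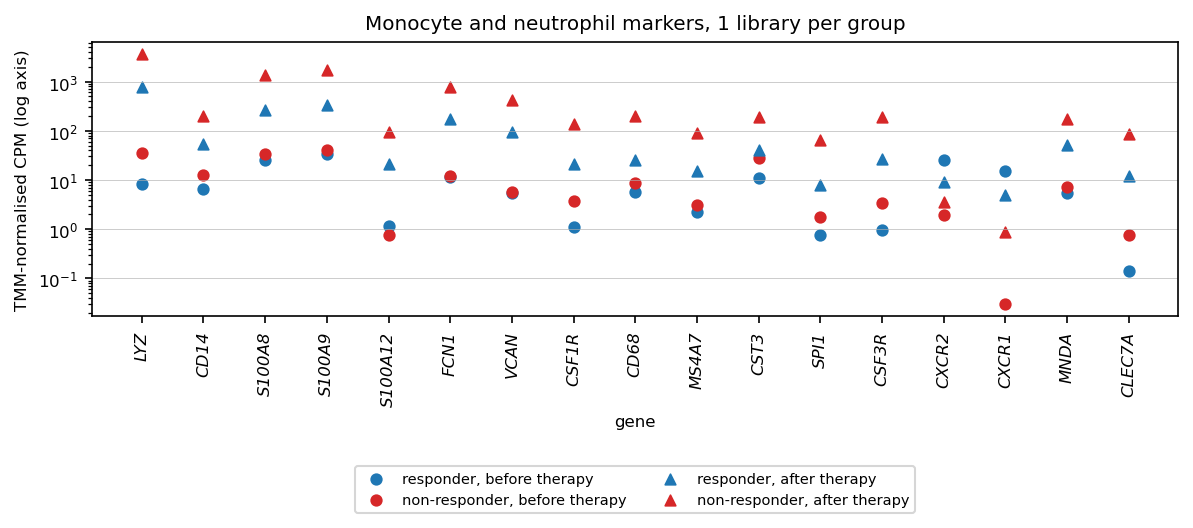
TMM-normalised CPM (log axis) of the 17 monocyte and neutrophil markers in the 4 libraries, with 1 point per library. Circles are libraries from before therapy, triangles from after therapy, blue responder and red non-responder, and both triangles lie above both circles for all markers but CXCR1 and CXCR2, with LYZ at 8.25 and 35.1 CPM before and at 791 and 3631 CPM after therapy.

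The medians of the cytotoxic and proliferation lists were lower after therapy in both groups. The 7 genes of the sort and label list had medians of -0.05 in responders and -0.09 in non-responders, both inside the random range. In each group 3 of these were higher after therapy, so this list showed no fall of like size. The same libraries differed in markers of other cells, with the monocyte and neutrophil medians of 3.39 and 5.22 after over before, and with the epithelial keratin KRT19 at 55.5 CPM in the responder library before therapy and no count after it. The cytotoxic genes had medians of -0.39 in responders, at percentile 0.13, and -0.67 in non-responders, below all random lists. FGFBP2, a gene of cytotoxic lymphocytes, stood at 174 against 433 CPM in responders and at 91.3 against 452 CPM in non-responders, and GNLY, which encodes granulysin, at 1320 against 4730 CPM in non-responders. The CX3CR1-type genes had medians of -0.12 in responders, inside the random range, and -0.42 in non-responders, at percentile 0.52. B3GAT1, the enzyme that makes the CD57 epitope of late effector cells, was 6.11-fold lower in responders and 10.7-fold lower in non-responders, and ZNF683, a transcription factor of tissue-resident and effector T cells, was 5.27-fold and 2.74-fold lower. The proliferation genes had medians of -0.75 and -0.82, below all random lists in both groups, with 8 members at least 2-fold lower in both. Over the proliferation genes with at least 10 CPM the median in responders was -0.32. MKI67 stood at 0.402 CPM after against 36.5 CPM before therapy in non-responders, and TK1, a thymidine kinase, at 4.23 against 18.0 CPM in responders. Other members were higher after therapy in non-responders, with CCNB2, a mitotic cyclin, at 1.97 CPM and no count before therapy, and AURKB at 0.795 against 0.0767 CPM. Ribosomal protein genes had medians of -0.41 and -0.38, and 46 of 55 were lower in both groups. The respiratory chain genes encoded in the nucleus had medians of -0.23 in responders, at percentile 0.19, and -0.18 in non-responders, at percentile 7.1.

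For other groups the values of responders and non-responders lay apart, and these differences between groups were not tested. Immediate early genes had a median of 0.56 in responders, at percentile 99.94, and of -0.10 in non-responders, inside the random range. CD69, an early activation marker, stood at 959 CPM after against 285 CPM before therapy in responders. Interferon-stimulated genes had a median of -0.03 in responders and of 0.43 in non-responders, at percentile 99.22, with RSAD2 at 27.1 against 1.04 CPM and OAS1 at 107 against 13.2 CPM in non-responders. CD4 and regulatory T cell markers had a median of 0.55 in responders, inside the random range at percentile 97.48, and of 1.35 in non-responders, at percentile 99.66. Over the members with at least 10 CPM the median in non-responders was 0.38, below that of responders. CD4, which monocytes also express, stood at 94.7 against 4.81 CPM in non-responders. These lists and the monocyte markers differed in the same libraries. Dendritic cell markers had a median of 0.52 in responders, inside the random range at percentile 91.24, or 0.97 with counts of 0 set at the floor, and of 5.02 in non-responders, at percentile 99.54, with FCER1A at 29.2 CPM after therapy and no count before it. Over the dendritic cell markers with at least 10 CPM the medians were 3.15 and 10.99, the latter resting on genes with no count before therapy, whose fitted ratio depends on the prior count. Heat shock and stress genes had medians of -0.09 and -0.33, the latter at percentile 2.34. B cell and plasma cell markers had a median of -1.83 in responders, at percentile 0.01, which turned to 1.32 over the members with at least 10 CPM.

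In responders, 1617 of 12265 genes were at least 2-fold apart between the times, 1042 higher and 575 lower after therapy. With libraries scaled by their totals alone, the higher share was 51.6% in place of 64.4%, and the median over all genes was -0.04 in place of 0.07. CD86, TFEC, NFAM1, DOK3 and VNN1 had no count before therapy. KRT19, PLAU, FSTL1 and CYR61 had no count after therapy, and KRT19, an epithelial keratin (ENSG00000171345), stood at 55.5 CPM in the responder library before therapy, at least 2360-fold higher. In non-responders, 3019 of 12641 genes were at least 2-fold apart, 1976 higher and 1043 lower after therapy. HK3, IL13RA1, CD1D, DOK3 and PTAFR had no count before therapy, and HK3, a hexokinase of myeloid cells, reached 86.1 CPM after it. CCL18, CXCL9, CHI3L1, ARHGEF10 and LONRF2 had no count after therapy, and the macrophage chemokine CCL18 had stood at 9.2 CPM before it. Lower after therapy in both groups by the naming rule were EFNA1, FHL2, MDK, SLC1A7, B3GAT1, ITGAD, ID3, SAMD1, TM4SF19 and A2M-AS1. ID3, a transcriptional regulator on the naive and central memory list, was 8.19-fold lower in responders and 5.58-fold lower in non-responders, while that list had medians of 0.06 and 0.16, both inside the random range.

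In the additive model, edgeR called 0 of 24113 genes between after and before, with 2732 at an unadjusted p under 0.05, DESeq2 called 1516, 1078 higher and 438 lower after therapy, and limma-voom called 2. LYZ and 1 gene known only by a clone name shared the lowest edgeR adjusted p, 0.111, LYZ with a log2 ratio of 6.64 ± 0.215 (SE). With genes limited to those with at least 5 CPM in 2 libraries, edgeR called 35 genes, 34 of them higher after therapy, and without a filter on low counts it called 2. Adjusted over the list alone, 15 of 17 monocyte and neutrophil markers and 6 of 17 CX3CR1-type genes passed, against 0 over all genes tested. The camera test called 7 of 25 lists, with an adjusted p of 2.81e-77 for the monocyte and neutrophil markers (adjusted p = 0.837 with an estimated correlation) and 0.000191 for proliferation (adjusted p = 0.837 with an estimated correlation). No list kept its call with an estimated correlation, which cannot decide at 1 residual degree of freedom.

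**Figure D5:**
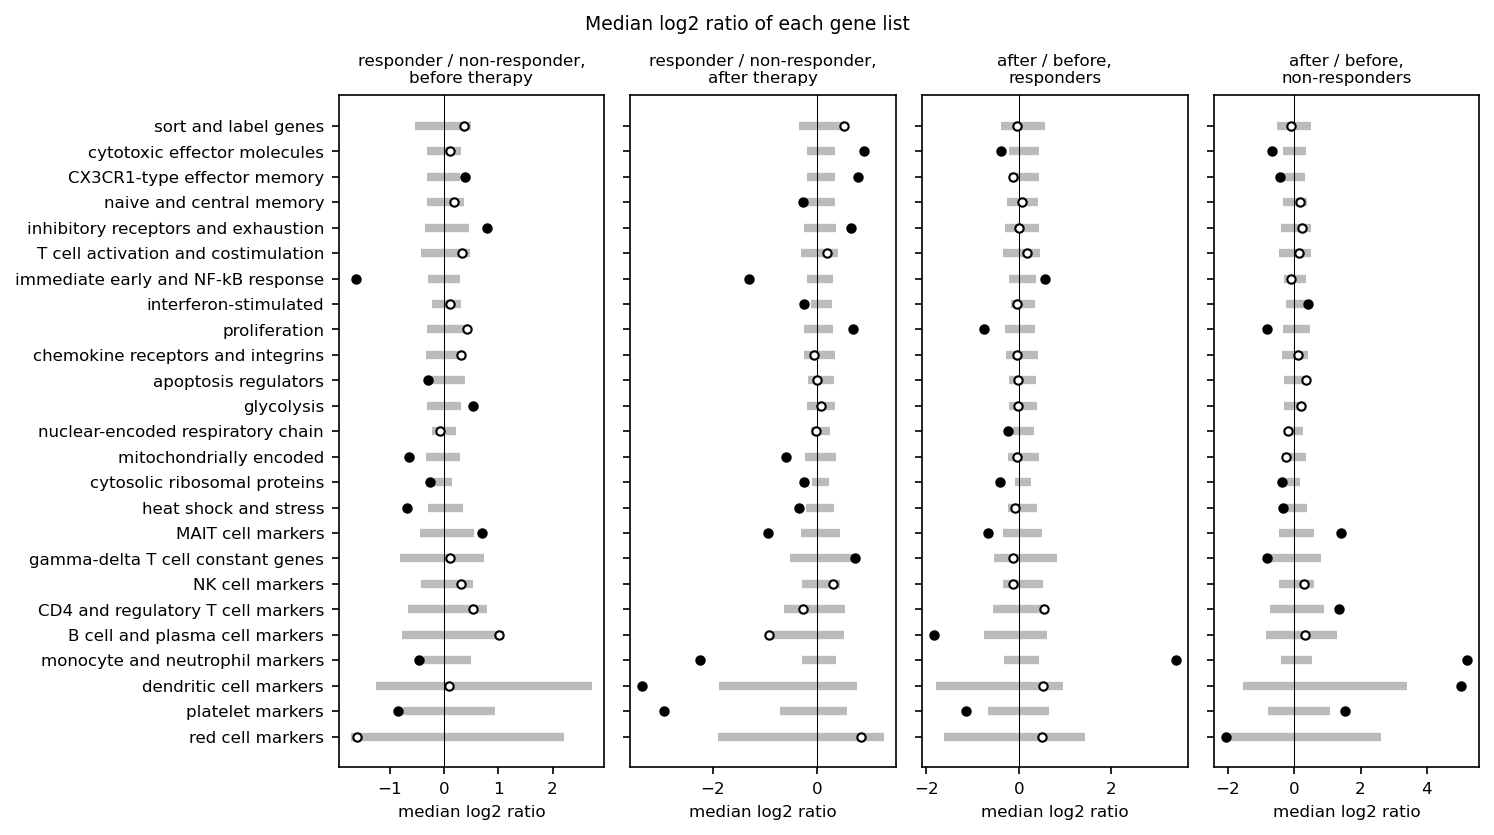
Median log2 ratio (x axis) of each of the 25 gene lists in each of the 4 comparisons of 1 library with another, with grey bars for the central 95% of 10000 random lists matched on mean expression. Filled points lie outside that range, 11 and 15 lists for responder over non-responder before and after therapy and 9 and 13 lists for after over before in responders and non-responders, with the monocyte and neutrophil markers at 3.39 and 5.22 in the last pair.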

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

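These differences were looked at only after their values were seen. MAIT cell markers went in opposite directions in the 2 response comparisons: the median log2 ratio of responder to non-responder was 0.70 before therapy, at percentile 99.34 of matched random lists, and -0.94 after therapy, below all of them. Put as time, the median was -0.66 after over before in responders and 1.40 in non-responders. IL23R, a cytokine receptor chain, stood at 5.52 CPM in the responder and 0.429 CPM in the non-responder before therapy, and at 1.33 and 6.05 CPM after it. CEBPD, a member of the list that monocytes also express, stood at 163 CPM in the non-responder after therapy. Platelet markers had a median log2 ratio of -1.14 after over before in responders and of 1.52 in non-responders, with ITGA2B at 20.6 CPM after and 0.0307 CPM before therapy in non-responders. With 1 library in each group, neither difference was tested.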

How the results depend on the processing

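No paired analysis was possible because the labels tie no libraries to the same patient and the groups compared share fewer than 2 replicate numbers. The additive model does take time, or response, as a covariate. The response test called 0 genes under each edgeR alternative and limma-voom, and 896 with DESeq2. The test of time called 0, except 2 without a filter on low counts, 35 with at least 5 CPM in 2 libraries, 2 with limma-voom and 1516 with DESeq2. With each library left out in turn, fitted without a covariate and with the lone library of an arm assumed to vary like the others, both tests called 0 genes in all 4 fits, with 506 to 3072 genes at an unadjusted p under 0.05 for response and 1085 to 3503 for time. The cause of these differences between tools was not tested. Simulated 4-fold changes were not recovered at the observed spread, so a count of 0 says little about changes of that size. Dividing the libraries the remaining way, chosen after seeing the data, also called 0 genes, with 476 at an unadjusted p under 0.05, against 1365 for response and 2145 for time without a covariate. The camera calls of 15 lists for response and 7 for time became 0 with an estimated correlation and 0 with fry.

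Genes at least 2-fold apart numbered 5252, 3765, 3586 and 5942 at a minimum of 1 CPM (response before, response after, time in responders, time in non-responders), 1260, 874, 797 and 1488 at 20 CPM, and 548, 540, 337 and 967 at 4-fold, as these settings change how many genes can count. The correlation of the response ratios was 0.497 at 20 CPM and 0.141 at 1 CPM, with 212 and 1045 genes 2-fold apart in the same direction. Of 460 alternative values of the single genes, 434 stayed within their counting interval and 26 moved, 25 of them at a prior count of 5. Of 296 alternative list medians, 288 stayed within 0.5 of the width of the random range and 7 moved. The B cell and plasma cell median for time in responders turned from -1.83 to 1.32 over members with at least 10 CPM. Lists outside the random range numbered 9 to 16 over all settings and comparisons.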

Other observations

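All tests of explanations here were chosen after the patterns were seen. Most detected epithelial markers had their highest level in the responder library from before therapy, whereas ELF3 was higher in the non-responder before therapy, at 3.22 against 2.26 CPM. The keratin genes KRT7, KRT8, KRT18 and KRT19 stood at 52.9, 41.2, 42.4 and 55.5 CPM there, at 3.45, 1.61, 3.42 and 3.10 CPM in the non-responder library before therapy, and at no more than 1.76 CPM after therapy. FN1, which encodes fibronectin, stood at 100.2 CPM against 4.34 CPM in the non-responder before therapy. In all, 33 genes were at least 10-fold higher in this library than in each of the others, against 5, 1 and 46 genes for the non-responder before, the responder after and the non-responder after therapy. The 46 genes of the last library included CEBPD at 162.5 CPM and CLEC12A at 114.0 CPM.

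The non-responder library from before therapy lacked single transcripts that the others held. Genes with at least 5 CPM in the other 3 libraries and under 0.1 of their lowest level in this library numbered 38, against 2, 0 and 2 for the responder before, the responder after and the non-responder after therapy. CCR2, HYAL2 and ZNF607 were among 4 genes with no count there, and it also had the fewest counts in all, 65500644.

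The lower immediate early and NF-kB genes in responder libraries were set against 4 explanations. Monocyte RNA could bring a median of 1.12% of the excess in the non-responder before therapy, taking the ratio of each gene to LYZ in the non-responder library after therapy, and at most 3.89% for any of the 21 genes, which argues against it as the cause at that time. For the pair from after therapy the same figure was 117%, nearly fixed by how it is computed, so there monocyte RNA and a change within the T cells cannot be told apart. Coding length does not account for it, since the list median nearer to 0 was -1.34 after adjustment for length, below all matched random lists. Stress in handling or sorting stays open, since the median of the separate heat shock and stress list was lower in responders too, nearer to 0 after therapy at -0.35. Of its 21 members, 12 were lower and 3 higher in the responder at both times, and monocyte markers differed in the pair from after therapy as well. A difference tied to response also stays open, and was not tested with 1 patient library per group.

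The monocyte transcripts after therapy are consistent with monocytes or their RNA among the sorted cells, although a gate on CD8 should remove monocytes: of 20 further monocyte genes on no other list used here, chosen as textbook genes after the pattern was seen, 95% (19 genes, all but TYMP) were at least 2-fold higher after therapy in both groups. The most abundant, LYZ, S100A9 and S100A8, stood at 3631, 1720 and 1370 CPM in the non-responder after therapy, and at 35.1, 40.4 and 33.6 CPM in the non-responder before it. No marker of the original list of 17 is on another list used here, though CD8+ T cells also express CXCR1 and CXCR2. A difference in sorting between the libraries from before and after therapy and an effect of therapy remain open, since both go with time. Whether cohort goes with time as well is not known, since the labels tie no cohort to a library.

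The epithelial transcripts were tested with a list of 20 epithelial markers written after epithelial genes such as KRT19 and CLDN4, and values of many of its members, had been seen. Markers under 1 CPM in every library were not counted as detected. Of these, CDH1 and CLDN3 were highest in the responder library from before therapy, and ITGB4, MUC1, ESRP1 and GRHL2 in another library. Of 14 detected markers, 85.7% were highest in the responder library from before therapy and at least 5-fold above both libraries from after therapy, which suggests RNA of epithelial cells, although the sort should remove them. Reads misassigned from the responder to the non-responder library before therapy would keep 1 ratio. The 4 keratins had 4.72% as many counts in the non-responder as in the responder library. However, 5 markers for which that gives at least 10 counts had none, LAMB3 with 27.9 expected among them. This speaks only to the low counts in the non-responder library, and cannot decide where the transcripts of the responder library came from. Reads misassigned from a library outside this series were not tested. Whether the RNA came with the blood sample or entered later was not tested, and no biological explanation was tested.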
